A study of Drosophila melanogaster with 2 samples.

How the data were processed

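Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos collected from 0 to 24 hours of development, from a transgenic strain that carries a fusion of castor (cas) with green fluorescent protein. Per the labels, an antibody against green fluorescent protein pulled down the tagged protein from chromatin sonicated to 200 to 800 bp. The series holds 1 group with 2 biological replicates, so no comparison between groups exists and every measurement below describes that group. Replicate numbers were taken from the labels. Input or mock libraries were not analysed here.

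Peak lists on assembly dm6 were used. A thresholded and a ranked list exist for each replicate, and a further 2 lists of each kind combine both replicates; the thresholded list named conservative per the deposited README texts was the main one, and the other combined list is called the pooled list. Per the deposited README texts, each list was derived from the alignments of the replicate or replicates it covers and from further files not used here. The aligner, the peak caller and its settings are not given in the sources used here. The ranked lists hold the irreproducible discovery rate (IDR), a measure of how reproducibly a peak ranks in a pair of peak sets, as -log10 values given by the authors, which end at 5. The score column of the deposited lists is the authors' scaled IDR value, at most 1000. The signal value of each peak is the authors' own measure of its height, not scaled between lists, and it was used only to describe, rank or filter peaks, and to correlate overlapping peaks across the replicates. On the files, each thresholded list held ranked entries with a -log10 IDR of at least 2, with some such entries missing. The coordinates of both peak sets behind the conservative ranked list were matched to the ranked lists of the replicates: 59707 entries of 105251 had the position of a replicate 1 entry on one side and 66152 that of a replicate 2 entry on the other, and no entry matched the opposite way. Which side belongs to which replicate is not stated, so the side values were used only in a symmetric correlation, and values quoted for a replicate come from that replicate's own lists.

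Read totals are not given in the lists, so the depth of each replicate is unknown. Intervals given for shares are 95% Wilson intervals over peaks and cover counting error only. Peaks and genes are not independent replicates.

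Positions were compared with the Drosophila melanogaster reference of Ensembl release 115 (BDGP6.54), whose chromosome arm lengths equal those of dm6. Peaks on the arms 2L, 2R, 3L, 3R, 4, X and Y were analysed and those on other contigs were counted only. Each summit received 1 class in the order promoter (within 500 bp of a transcript start), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. Class shares were compared with 1000 random placements of the summits within their own arm (two-sided permutation). Replicate overlap, of at least 1 bp, was compared with 1000 placements of one list (one-sided permutation). Peak numbers per arm were tested against the arm's share of called bases by an exact two-sided binomial test. A protein-coding gene was said to have a peak when a summit lay in its body or within 2 kb of it. The number of such genes in each of 17 lists was compared with 10000 random lists of the same size matched on gene length in 20 bins (one-sided permutation). For DNA words, the 101 bp around each summit were paired with a 101 bp window 500 bp away on a side drawn at random. All 2080 words of 6 bases, each joined with its reverse complement, were compared by an exact two-sided binomial test of discordant pairs, in which only the centre or only the flank had the word. Fixed words were tested the same way. P-values were adjusted by the Benjamini-Hochberg method within each family with a threshold of 0.05.

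Named genes followed a fixed rule: the genes of the 20 strongest conservative peaks (the gene whose body holds the summit and the gene with the nearest start), up to 4 members of each list with the strongest peaks, and cas. A gene named outside that rule is said to be so. Of the listed symbols, 2 were matched through an older name and 3 had no protein-coding gene of their own. Groups, tests, gene lists, fixed words and the alternatives were chosen before the data were examined, except where the text says otherwise. The alternatives were other overlap rules, promoter windows of 200 and 1000 bp, the pooled list, the upper 50% of peaks by signal, the list of each replicate alone, other rules for assigning peaks to genes, Fisher's exact test without the length match, a 51 bp window, a dinucleotide-preserving shuffle of each centre in place of the flank, and margins of 2 and 50 kb around cas. After the data had been seen, lists without peaks of signal under 10 and the ranked entries that did not pass were added as alternatives.

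Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The procedures were tested on simulated data. Random places and windows gave 0 location classes and 0 words past the threshold, and a planted promoter share of 65.7% was read as 65.5%. All 50 lists with 10 of 20 members planted as genes with a peak were called, against 0 of 50 random lists. Shorter lists and smaller planted shares were not simulated, so the power to find them is unknown.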

Results

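Castor is a zinc-finger transcription factor of the temporal series that embryonic neuroblasts, the stem cells of the nerve cord, express in turn. Its occupancy in whole embryos of 0 to 24 hours was measured by immunoprecipitation of a castor fusion with green fluorescent protein, in 2 biological replicates of a single group. Because whole embryos were used, each peak averages over all tissues and stages of the collection. The depth of the replicates is unknown, since the lists give no read totals.

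The conservative list held 1880 thresholded peaks, of which 1879 lay on the chromosome arms, with a median width of 310 bp and a summed length of 557 kb. The pooled list held 2237 peaks, and 1685 of the conservative peaks (89.6%) were also in it. Called alone, replicate 1 gave 1248 peaks and replicate 2 gave 1158. The authors' signal values, which are quoted throughout as given, had a median of 77.3 in the conservative list and ran from 2.07 to 1218. Of the 47 conservative peaks of signal under 10, 46 rested on the same pair of replicate peaks as a stronger entry. A peak at X 6744329-6744638 with signal 2.07, for example, rested on the same pair of replicate peaks as a neighbour at X 6744127-6744436 near the start of RpL17, whose signal was 75.7 (a region chosen after its values were seen). The 1880 peaks rested on 1801 distinct pairs of replicate peaks.

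The strongest peak, with signal 1218, lay in an intron of CG11050 on 2L (6612532-6612878, summit 6612711), and reached 629 in replicate 1 and 578 in replicate 2. The 41 bases around that summit were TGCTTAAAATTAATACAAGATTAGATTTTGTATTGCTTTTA. Next came a promoter peak 32 bp from the start of Ugalt, a UDP-galactose transporter gene (X 2703740-2704025, signal 1068), with the summit sequence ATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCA. The peak after these, with signal 909, lay at the promoter of mRpL41, which encodes a mitochondrial ribosomal protein (2R 15217630-15217898). CG14100 (837) and CIA30 (680), a gene for an assembly factor of respiratory complex I, followed. None of the 20 strongest peaks had a member of a fixed gene list as its gene.

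The Polycomb group gene ph-p had an intronic peak of signal 642 (X 2137240-2137477), Adf1, a transcription factor gene, had an intronic peak of 537 (2R 6662945-6663193), and Tlk, a chromatin-associated kinase gene, had one of 475 (X 3742100-3742348). Chro, which encodes a protein of decondensed interband chromatin, had a promoter peak of 475 (3L 22878786-22879001), and Sox14 had one of 469 (2R 23978451-23978680). The remaining peaks were at Tcs5 (635), CenG1A (604), CG32772 (589), PNPase (578), CG5611 (573), CG13390 (556), the arginine methyltransferase gene Art3 (555), the glutathione transferase gene GstE13 (529), Fkbp14 (482) and CG18549 (469). Of the 20 summits, 15 lay in promoters and 5 in introns. The log2 ratio of replicate 1 to replicate 2 over these peaks had an SD of 0.34.

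How far the replicates found the same regions was asked from their own lists. Of the 1248 peaks of replicate 1, 762 (61.1%, Wilson interval 58.3 to 63.7) overlapped a replicate 2 peak, against 0.464% ± 0.191 (SD) over 1000 random placements (one-sided permutation p = 0.001, the smallest possible). In the other direction 756 of 1144 arm peaks (66.1%, 63.3 to 68.8) overlapped, against 0.508% ± 0.206 (p = 0.001, also the smallest possible by permutation). Shared peaks were stronger than the others, with a median signal of 61.0 against 40.3 in replicate 1 and 62.0 against 41.6 in replicate 2. Of the 486 unshared replicate 1 peaks, 440 overlapped an entry of the ranked list of replicate 2, thresholded or not, as did 357 of the 388 unshared replicate 2 peaks in the ranked list of replicate 1. The ranked lists are long, with 58485 entries for replicate 1 and 89597 for replicate 2. The overlap that random places would have with them was not measured.

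Across the 762 overlapping peaks, which are not independent replicates, the signal of the replicates had a Spearman rho of 0.705 (bootstrap 95% interval 0.662 to 0.745). The log2 ratio of replicate 1 to replicate 2 had a median of -0.02 and an SD of 0.55, and summits lay a median of 23 bp apart. Over all 105251 entries of the ranked list that compares the replicates, rho was 0.210. Of the conservative peaks, 772 (41.1%) overlapped a peak of both replicate lists, 320 of replicate 1 alone, 280 of replicate 2 alone and 507 (27.0%) of neither. The replicate lists used here are thresholded on their own IDR values. Overlap with neither therefore does not mean that a region was unseen in the replicates.

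The location of the summits was compared with random places on the same arm. Promoters held 1166 of the 1879 summits (62.1%, Wilson interval 59.8 to 64.2), against 13.4% ± 0.751 (SD) at random, a 4.62-fold excess. Introns held 499 summits (26.6% against 39.5%) and intergenic sequence 161 (8.57% against 27.4%). Coding exons held 17 (0.905% against 13.1%) and 3′ UTRs held 13 (0.692% against 5.08%). Each of these 5 classes differed from random with the smallest p that the two-sided permutation could give, 0.002 (adjusted p = 0.0028). The fold of 3′ UTRs went from 0.136 to 0.0865 without replicate 1 and that of coding exons from 0.0693 to 0.0367 without replicate 2. In the pooled list the coding exon fold was 0.171 and in the upper 50% by signal 0.0326, and all of these still passed. The 8 summits in 5′ UTRs (adjusted p = 0.100 by permutation) and the 15 in other exons (adjusted p = 0.965) did not pass. Among the ranked entries that did not pass the IDR threshold, a background chosen after the data were seen, 17.2% of 102664 summits lay in promoters. Against that background the 5′ UTRs did pass, as less frequent (0.426% against 1.04%, adjusted p = 0.00627, Fisher's exact test).

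**Figure D1:**
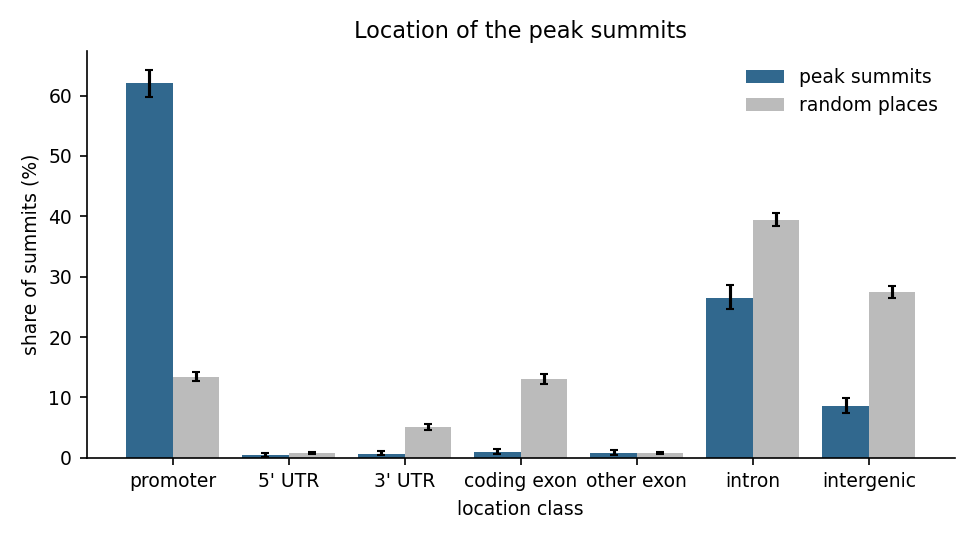
Share of the 1879 conservative summits in each location class (blue, with 95% Wilson intervals) and of the same number of random places on the same arms (grey, mean and SD of 1000 placements), in percent. Promoters held 62.1% of summits against 13.4% of random places.

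Summits gathered just upstream of transcript starts. Of the 1109 summits within 500 bp of a protein-coding start, 910 (82.1%) were upstream, at a median of -95 bp and with quartiles of -163 and -29 bp. The fullest 25 bp bin, from -100 to -75 bp, held 131 summits. The promoter share was 73.3% among the 187 strongest peaks and 54.0% among the 187 weakest. Promoter peaks had a median signal of 82.1, intronic ones 73.2 and intergenic ones 70.7. A group of 583 summits (31.0%) lay over 1 kb from every protein-coding start.

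**Figure D2:**
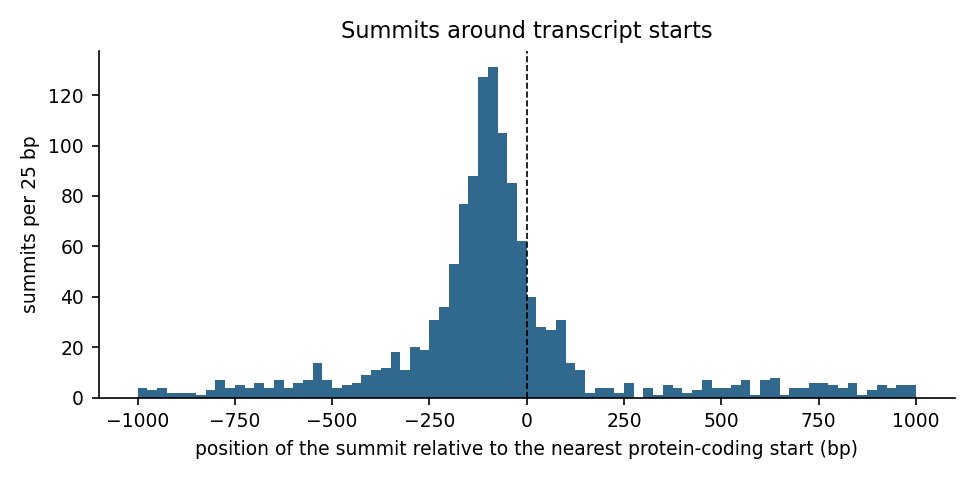
Number of summits in 25 bp bins (vertical axis) by position relative to the nearest protein-coding transcript start in bp (horizontal axis, negative is upstream, the dashed line is the start). The fullest bin, from -100 to -75 bp, held 131 summits.

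Peak densities on the large arms lay close together. The values per megabase were 14.8 on 2L, 13.96 on 2R, 14.1 on 3L, 13.6 on 3R and 14.7 on X, and none passed the exact two-sided binomial test (adjusted p from 0.248 to 0.827). The small arm 4 held 1 peak against 18.2 expected (adjusted p = 1.42e-06, exact binomial test). Its fold of 0.0548 rose to 0.180 without replicate 1 (adjusted p = 0.00762, exact binomial test) and to 0.330 without replicate 2 (adjusted p = 0.0465). The Y held 0 against 46.7 (adjusted p = 4.16e-20, exact binomial test), where a count of 0 allows up to 3 peaks. The expected number counts called bases only. How well reads can be placed on the Y and its number of copies in the collected embryos were not taken into account. The 0 therefore does not show that binding is absent there. Without replicate 1 the fold on the Y was 0.0351. In the pooled list and in replicate 2 alone, 2L also passed, with 1.12 and 1.16 times the expected number.

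Which kinds of genes carried peaks was asked with 17 lists. Over the genome, 2808 of 13968 protein-coding genes (20.1%) had a summit in the body or within 2 kb. Ribosomal protein genes had one in 50 of 92 cases (54.3%), against 14.2 ± 3.41 (SD) in length-matched random lists. That 3.52-fold excess was the only one to pass (one-sided permutation p = 0.0001, the smallest possible, adjusted p = 0.0017). Among their stronger peaks, signals were 261 for RpL3 (3R 11226599-11226731), 187 for RpL7 (2L 10200970-10201096) and 184 for RpL32 (3R 30046118-30046427). All of these were promoter peaks, but that of RpL3 was nearest to the start of CG17726. When each summit was given to the gene with the nearest start, 37 ribosomal protein genes had a peak, a 5.75-fold excess.

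No list of the neural programme in which castor acts passed the test for more peaks than matched genes. In the temporal series, 1 of 10 had a peak against 2.85 ± 1.39 expected: grh, the last member of the series, with an intronic peak of 76.3 (2R 17804794-17805103). The other 9, among them hb, Kr, nub, pdm2, svp and cas, had none in the conservative list (the first 5 were chosen after their values were seen). Of 20 neuroblast and progenitor genes, 3 had peaks against 4.64 ± 1.86 expected: brat (206, intron), numb (124, promoter), both involved in the asymmetric division of neuroblasts, and insc (69.8, intron). Of 23 regulators of neuronal identity, 4 had peaks against 7.03 ± 2.17: zfh1 (116, intron), tup (111), sqz (97.2) and eya (54.4). The insc, tup and sqz summits were nearest to the starts of sktl, CG10602 and Nsun5. Of 20 neuronal function genes, 2 had peaks against 6.40 ± 2.07, the RNA-binding protein gene elav with 266 at its promoter (X 523389-523575) and the synaptobrevin gene nSyb with 101.02. The nSyb summit lay outside the gene, nearest to the start of Bgb. Without replicate 2 there were 4 neuronal function genes with a peak (fold 0.875, against 0.312 in the main list) and 0 of the temporal series. Adjusted p was 1 for each of these 4 lists in the planned one-sided permutation. In the lower tail, a permutation test added after the data were seen, it ran from 0.0986 (neuronal function genes) to 0.433 (neuroblast and progenitor genes).

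Glial genes had peaks in 4 of 12 cases against 3.15 ± 1.51 expected. They were moody (317, promoter, X 2050190-2050367), a receptor gene of the blood-brain barrier, the glutamine synthetase gene Gs2 (137, intron), bdl (82.4, nearest to the start of Atet) and pnt (75.6). The Notch pathway list had 5 of 16 against 3.59 ± 1.61, with E(spl)m8-HLH (149), mam (114), neur (96.2) and the receptor gene N (64.8) as the strongest. The summit counted for E(spl)m8-HLH lay 103 bp from the start of gro. Those of mam and N, both in introns, were nearest to the starts of CG18371 and CG18508. Without replicate 2 the Notch list had 2 genes with a peak (fold 0.787, against 1.39 in the main list). Ecdysone response genes had peaks in 5 of 14 cases against 4.71 ± 1.74, led by the nuclear receptor genes Hr3 (208), Hr4 (112), usp (68.9) and Eip75B (63.3). The Hr3 summit, in an intron, was nearest to the start of CG46321. Mesoderm and muscle genes had 5 of 17 against 4.85 ± 1.84, with Mef2 (272, nearest to the start of Pdrg1), tin (164), sls (114.6) and bin (66.6). Adjusted p was 1 in the one-sided permutation for each.

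No list of patterning genes or of markers of other tissues passed. None of 18 gap and pair-rule genes had a peak, against 4.01 ± 1.74 expected. Segment polarity genes had 3 of 14 against 4.10 ± 1.70, nkd (123.4), lbl (61.9, nearest to the start of CheB93b) and ptc (38.0), and Hox genes 1 of 8 against 2.74 ± 1.35, Antp (53.6). The haemocyte and fat body list had ush alone (70.4) of 13 against 3.72 ± 1.61, the trachea and epidermis list shn (131) and grh of 16 against 4.91 ± 1.85, and the midgut list bowl (161) of 9 against 2.65 ± 1.37. Without replicate 1 the gap and pair-rule list had 1 gene with a peak, the segment polarity list 1, the haemocyte list 0 and the Hox list 1 (fold 0.549, against 0.364). Without replicate 2 the segment polarity list had 1 and the Hox list 0. Adjusted p was 1 for all 6 lists in the planned one-sided permutation, and from 0.0544 to 0.532 in the lower tail, a test added after the data were seen.

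Genes of late cuticle and of the chemical senses held fewer peaks than matched genes in a test of the lower tail that was added after the data were seen. Cuticle protein genes had 2 of 112 against 16.4 ± 3.68 expected, Cpr76Ba (131) and Cpr73D (59.9). The Cpr73D summit, in an intron, was nearest to the start of Ogdh. Odorant and gustatory receptor genes had 5 of 119 against 21.3 ± 4.11, with Or85f (137), Or88a (92.1), Gr89a (88.7) and Or9a (63.7) as the strongest. The Or85f summit was that of the RpL34b promoter, and those of Or88a and Or9a were nearest to the starts of CG12402 and Neb-cGP. Both had an adjusted permutation p of 0.00085, while the gap and pair-rule genes missed the threshold (adjusted p = 0.0544). Without replicate 1 the receptor genes had 2 with a peak (fold 0.124, against 0.235) and still passed. With nearest starts, the receptor genes no longer passed (fold 0.399, adjusted permutation p = 0.200).

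**Figure D3:**
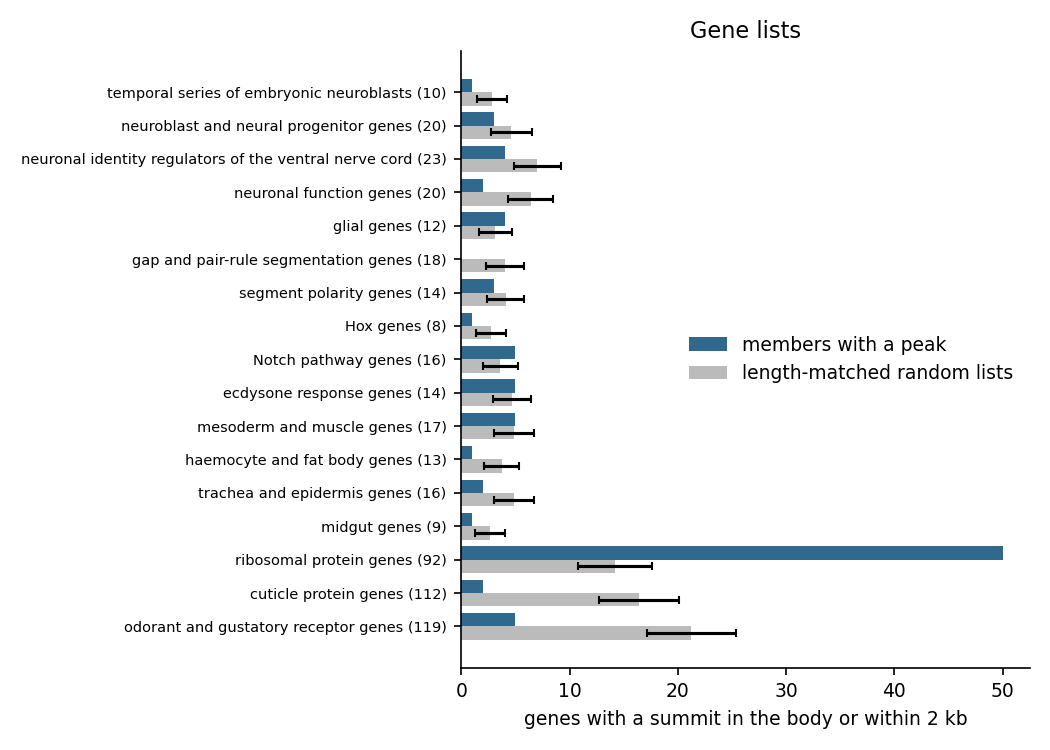
Number of genes in each fixed list with a summit in the body or within 2 kb (blue) and in length-matched random lists (grey, mean and SD of 10000 lists); the number of measured genes is in brackets. Ribosomal protein genes had 50 against 14.2, cuticle protein genes 2 against 16.4.

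The cas gene itself, which lies at 3R 5712975-5716805 on the minus strand, had no conservative peak within 10 kb, and none in the list of either replicate. The pooled list had 1, at 3R 5716278-5716587, with signal 50.8 (30.9 in replicate 1 and 20.4 in replicate 2). Its summit lay in the promoter class, 372 bp downstream of the nearest start, in the sequence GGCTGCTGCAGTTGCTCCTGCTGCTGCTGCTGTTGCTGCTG, of which 63.4% was G or C. Within 10 kb the conservative ranked list had 25 entries, or 1.05 per kb against 0.761 per kb over the genome. Within 50 kb there were 2 conservative peaks.

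DNA at the summits was rich in A and T. The central windows had a mean G and C content of 35.3% ± 10.6 (SD over 1879 windows), against 43.9% ± 10.6 in the flanks and 42.1% over the arms. Against the flanks, 298 of 2080 words were over-represented and 572 under-represented, and the 20 words with the smallest p were all made of A and T alone. ATTTTA led, present at 31.5% of centres and 12.7% of flanks (adjusted p = 3.98e-40, exact two-sided binomial test), followed by TTAAAA with 33.3% and 14.2%. Against shuffles that keep the dinucleotide content of each centre, 84 words were over-represented, 36 of them also against the flanks. The leader there was TATCGA, at 9.53% of centres and 3.25% of shuffles (3.36 times as many centres as shuffles among discordant pairs, adjusted p = 8.62e-13, exact binomial test), and the overlapping words ATCGAT and CGATAG were both at 6.97% of centres against 1.92% and 2.02% of shuffles. Split by place after the data were seen, TATCGA passed at the 1166 promoter summits (12.3% against 3.86%, ratio 3.91, exact binomial p = 4.89e-15). CGATAG led at promoters (10.5% against 1.80%, ratio 8.21, adjusted p = 1.35e-17, exact binomial test). At the 517 summits over 1 kb from any start TATCGA did not (5.42% against 3.29%, ratio 1.69, exact binomial p = 0.126). Its discordant pairs at both places gave p = 0.0271 (Fisher's exact test, two-sided, added last, not adjusted). TATCGA had been picked over all summits, most of them at promoters, so this test is biased towards a difference. The overlapping word ATCGAA passed at the distant summits (9.09% against 3.09%, ratio 3.58, adjusted p = 0.0344, exact binomial test) and had a lower ratio at promoters (6.86% against 4.55%, ratio 1.56, exact binomial p = 0.0187, not adjusted). Fisher's exact test gave p = 0.0266 for ATCGAA and 0.0273 for AATCGA, but both had been picked at the distant summits, which favours a lower ratio elsewhere. AAATAT, the leader against shuffles at the distant summits, had ratios of 2.00 there and 1.92 at promoters.

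**Figure D4:**
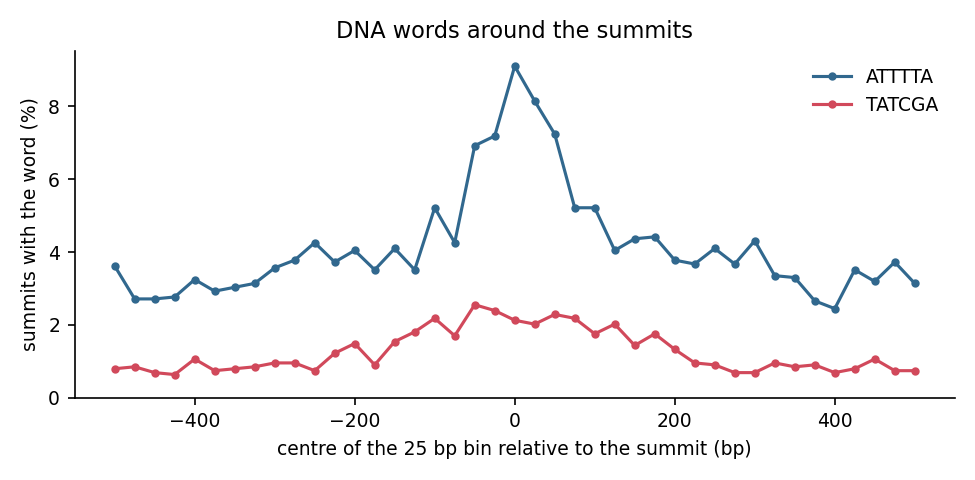
Percentage of the 1879 conservative summits with the word ATTTTA (blue) or TATCGA (red), on either strand, in 25 bp bins centred at each distance from the summit in bp. ATTTTA was found in 9.10% of bins at the summit and in 3.14% at +500 bp, TATCGA in 2.13% and 0.745%. At -500 bp the shares were 3.62% and 0.798%. TATCGA was highest not at the summit but at -50 bp (2.55%).

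Of the 10 words fixed beforehand, TTATCGATA, the binding site of the factor DREF, had the largest ratio. It occurred at 1.28% of centres and 0.106% of flanks, or 24 centres alone against 2 flanks alone (adjusted p = 3.50e-05, exact binomial test), and against shuffles the ratio of discordant pairs was 8 (adjusted p = 0.000246). In the upper 50% of peaks by signal its ratio was 6 and did not pass (adjusted p = 0.156, exact binomial test). TTTTTT, an A/T run like the sites of hunchback (26.1% against 17.99%), the homeodomain word TAATTA (9.42% against 5.48%) and CATAAA (12.03% against 8.73%) were more frequent at centres than in flanks. The GAGAG word of Trithorax-like (10.4% against 14.8%) and the E-box CAGGTG (2.71% against 5.43%) were less frequent. The calls of TAATTA with the 51 bp window (adjusted p = 0.0831, exact binomial test here and below) and of CATAAA in the pooled list (0.0841) were lost. That of CAGGTG was lost with the 51 bp window (0.0831), in the upper 50% by signal (0.136) and without replicate 2 (0.115). Against shuffles all 5 of these turned their direction, with CATAAA and CAGGTG no longer past the threshold (adjusted p = 0.0771 and 0.195, exact binomial test). The E-box CAGCTG, with 4.26% of centres against 5.27% of flanks (adjusted p = 0.211, exact binomial test), was 2.30 times as frequent as in shuffles among discordant pairs. It passed as less frequent than in flanks without replicate 2 (ratio 0.5 against 0.8 in the main list, adjusted p = 0.00515, exact binomial test) and in the upper 50% by signal (0.56, adjusted p = 0.0337). CAGGTA, the site of Zelda, did not pass against flanks (ratio 0.619, adjusted p = 0.0973, exact binomial test), but was less frequent than in shuffles (0.463, adjusted p = 0.00489). In the pooled list it passed against flanks (0.588, adjusted p = 0.0428, exact binomial test). ATTTGCAT and TGACATT passed against neither (the ratio of ATTTGCAT against flanks was 1.12, and 1.82 without replicate 2).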

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

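All tests in this part were chosen after the missing entries had been seen, and before the values they measure were known. Of the 1951 entries of the conservative ranked list that pass the IDR threshold, 71 are missing from the thresholded list and enter no comparison above. The strongest, with signal 854, lay in an intron at 2L 480953-481239, nearest to the start of cbt, and reached 477 in replicate 1 and 393 in replicate 2. It would have ranked among the 20 strongest peaks. Others of high signal were nearest to Lk6 (460), larp (398), CG18428 (371), trx (289) and tara (217), all on 3R. These genes were chosen after their values were seen. Of the 66 missing entries on the arms, 39 lay on 3R and 19 on 2L, and 54.5% were within 500 bp of a transcript start. Replicate 2 further had 14 thresholded peaks on contigs outside the arms, which were not analysed.

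Repeated sequence argued little for the loss: the 51 bp at the summit were found more than once in the reference for 2 of the 66 entries, 3.03% (Wilson interval 0.835 to 10.4), where over 50% would be needed. Among 300 kept peaks drawn at random it was 2 (0.667%). Removal by place remains open and may account for it. Of the 299 missing entries over the 4 ranked lists, 0% overlapped a peak kept in any thresholded list, which is what a fixed set of excluded regions would leave. The 4 lists come from the same replicates, so a region can be counted more than once among these entries. No list of excluded regions was used here, and no biological explanation was tested.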

How the results depend on the processing

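The alternatives without peaks of signal under 10 and with entries that did not pass as background were chosen after seeing the data. Of 41 values of the main results under alternatives, 38 were counted as kept. For a test this meant the same direction and side of the threshold, and for rho a value in the bootstrap interval. A count had to stay within a fixed fold of the main one. A kept count need not hold the same members: 6 fixed words passed against flanks and 6 against shuffles, but not the same ones. Of 281 values of single classes, arms, lists and words, 261 kept their side of the threshold, and their direction if they passed. Direction was not compared where neither value passed. The Notch list, for example, crossed from 1.39 to 0.787 without replicate 2. The replicate overlap ran from 56.6% to 67.6% and the promoter excess from 3.10-fold (window of 1000 bp) to 8.02-fold (200 bp); without replicate 1 and without replicate 2 it was 4.94 and 4.82. The list past the upper threshold was that of the ribosomal protein genes under all 8 alternatives run, with folds from 2.70 to 5.75. The 3 changed values were rho over all ranked entries (0.210), which adds the many entries that did not pass, the words over-represented against shuffles (84), and the conservative peaks within 50 kb of cas (2), a wider region. Against shuffles, 6 fixed words turned: GAGAG to 1.38, TTTTTT to 0.805, CATAAA to 0.822, CAGGTG to 1.40, CAGCTG to 2.30 and TAATTA to 0.736. A shuffle has the base content of the centre and a flank does not, but the cause was not tested for each word. TTATCGATA gave no ratio without replicate 2, since no flank alone had it. No paired analysis was possible because there is a single group. Unknown depth limits what the absence of a peak can show.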

Other observations

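All gene families, word comparisons with other starts and pairs of starts in this part were chosen after the main results had been seen, and before the values below were known except for the shuffles of windows at other starts, which were added after the values at promoter centres were known. Beyond the ribosomal proteins of the cytoplasm, other families of constitutively used machinery were looked at. Mitochondrial ribosomal protein genes had a peak in 23 of 73 cases against 9.69 ± 2.87 (SD) in length-matched lists (2.37-fold, adjusted permutation p = 0.0014), with mRpL41 at 909, mRpS23 at 604 and mRpS10 at 555. Nuclear RNA polymerase subunit genes had 12 of 30 against 4.98 ± 2.00 (2.41-fold, adjusted permutation p = 0.0056), led by Polr2C and Polr3G at 604 and 163. The peak counted for both mRpS23 and Polr2C is the one nearest to CenG1A, and that of mRpS10 the one nearest to Art3. Translation initiation factors had 15 of 44 against 8.96 ± 2.65 (adjusted permutation p = 0.0544) and did not pass, nor did complex I (10 of 40), vacuolar ATPase (9 of 33), proteasome (10 of 48) and aminoacyl-tRNA synthetase genes (8 of 33), with adjusted p from 0.133 to 0.386. When summits were given to the nearest start, neither of the passing families did so (5 mitochondrial genes, 1.21-fold, adjusted permutation p = 0.561, and 6 polymerase genes, 2.49-fold, adjusted p = 0.190).

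A hypothesis was that the peaks favour genes of other constitutively used machinery too. It needed at least 5 of the 7 families past the threshold, and at most 1 would have argued against it. The number was 2, so the test leaves it open.

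The placement of most summits within 500 bp of a transcript start was weighed against technical causes. The ranked entries that did not pass had a promoter share 44.9 percentage points lower (95% interval 42.7 to 47.1). This argues against the peaks sharing the background of those entries. Regions recovered easily in both replicates would pass the threshold and be missing from that background, so the test cannot decide about them. Recovery of open promoters with no preference for DNA words would have been argued against, by the test written before, if TTAAAA, the word with the smallest p against flanks at 517 summits over 1 kb from any start, passed at promoter centres, and it did pass there, against flanks (ratio of discordant pairs 4.21, exact binomial p = 1.70e-40) and against shuffles (1.33, p = 0.00717). That bound was set wrongly, because 11153 windows at the same distances from starts of genes without a peak also passed against their shuffles in the test added after those values were known (TTAAAA 1.11, exact binomial p = 0.00655, which the promoter centres exceed 1.2 times, 95% interval 0.966 to 1.49), and so did AAATAT (1.69, p = 3.55e-41), which passed at distant summits (2.00, adjusted p = 0.00935) and at promoter centres (1.92, adjusted p = 3.91e-07), and TATCGA (3.12, p = 9.71e-74, exceeded 1.25 times at promoter centres, 95% interval 0.841 to 1.87). By share of windows, TTAAAA was at 34.8% of promoter centres and 22.8% of those other windows (ratio 1.53) and TATCGA at 12.7% and 8.83% (ratio 1.44, 95% interval 1.22 to 1.70, which spans the bound of 1.5 set for it), but the other windows were richer in G and C (39.8% against 35.8%) and whether those starts are open was not measured, so a preference for these words and a property of promoters in general cannot be told apart.

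Another hypothesis was that the peaks favour starts shared by head-to-head gene pairs. Of 1047 genes nearest to a promoter summit, 51.8% had a divergent start within 1 kb upstream, against 33.8% of the other 12921, a ratio of 1.53, just above the bound of 1.5 set for it (Fisher's exact test, two-sided, p = 3.47e-30, with genes that are not independent). The ratio met the bound set for such a preference. Fisher's exact test concerns a difference from a ratio of 1, and no interval of the ratio was set against the bound. Whether those starts are also the more active ones was not tested, and a castor-specific cause is not separated from a general one by these lists, which come from a single tagged protein.

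Peaks of signal under 10 in the conservative list may have passed because they overlap the same replicate peaks as a stronger entry. Of the 47, 46 (97.9%) shared both replicate peaks with an entry of higher signal. Their own median signal was 4.55, while that of the stronger entry was 67.2.

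Near tRNA genes, 12 of 290 had a summit within 500 bp, against 4.03 ± 2.60 (SD) in 200 random placements (one-sided permutation p = 0.0149, not adjusted, and tRNA genes lie in clusters). Random placement ignores that summits lay within 500 bp of transcript starts in general 4.62 times as often as random places. The values therefore do not show a preference for tRNA genes.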
